A study of Mus musculus with 6 samples.

How the data were processed

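Nuclear RNA was sequenced from atrial cardiomyocyte nuclei of mice aged 8 to 12 weeks. Nuclei from the left and right atria of each animal were pooled, stained for PCM1 (a protein that accumulates around cardiomyocyte nuclei) and sorted by flow cytometry. The 6 libraries came from 3 control and 3 Prrx1(R1A)-/- animals, with 1 library per animal. Per the labels, RNA was extracted with the ReliaPrep kit, libraries were made with the Ovation RNA-seq System V2 and sequenced on a HiSeq4000. Per the labels, the authors used STAR and DESeq2 with the mouse genome build mm10; their versions, the read counter and the gene annotation are not given in the sources used here.

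The deposited table of expression holds 1 signal value per gene and library, which the sheet name calls a normalized count. Each deposited column is a whole multiple of 1 step per library within a tolerance of 0.01 reads, so reads per gene were recovered by dividing by that step. The single exception among all values is Prrx1 in control replicate 3. Where the count-based tools were used, reads were rounded to whole numbers. The authors' deposited comparison table lists 1900 genes, all with a p under 0.05, and gives for each the mean signal, the log2 fold change and its standard error, the Wald score, the p-value with its adjusted p-value, and the −log10 of the adjusted p-value. It states the fold change as Prrx1(R1A)-/- against control, as the signs of the deposited counts show, and codes the Wald statistic with the opposite sign. Of 26332 genes with values, 14584 reached a normalized count of at least 10 in at least 3 libraries and were tested. A further 847 entries with an identifier and no value were left out.

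The test was limma-trend (limma 3.58.1 in R 4.3.3) on the log2 of the deposited normalized count plus 1, with genotype as the single term. It was two-sided, with Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Errors of fold changes are the standard errors of this fit, and errors of counts are standard deviations over 3 libraries. For Prrx1 the exact permutation test over the 20 labelings of the 6 libraries was run as well; its smallest possible two-sided p is 0.1. Total reads per library ranged from 10580961 to 14658584, and from 6465255 to 9807543 once ribosomal RNA (Rn45s, Rn18s, Rnr1 and Rnr2) was left out. A count of 0 in a library allows up to 3 reads, which came to between 2.22 and 3.77 normalized counts. Intervals at 95% and this limit cover counting error only, because amplified reads are not independent molecules. Gene positions and overlaps are those of GRCm38; strand was not kept by the library method, so reads of the 4286 tested genes that share exonic bases with a gene on the opposite strand cannot be assigned to 1 strand.

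Before the data were examined, the test, 38 gene lists, the rule for named genes and most alternatives were fixed. The rule names Prrx1, the called genes, and, for a direction with fewer than 5 called genes, the 10 with the smallest p among genes with a mean count of at least 100 and groups that did not overlap, leaving out provisional gene names. From each list it takes the called members, or otherwise the 2 with the smallest p, and it takes each listed neighbour of Prrx1 with a mean of at least 10. Lists with at least 5 tested members (35 of the 38) were tested with camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. The mitochondrially encoded list was matched through the reference gene table after the data were seen, because the gene names in the files lack the usual prefix.

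Alternatives were other pseudocounts (0.5 and 5), no filter or a filter at 50, TMM, median and quantile scaling, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, library quality weights, the replicate number as a block, stricter thresholds, removal of mitochondrial, ribosomal protein and haemoglobin genes, and leaving out each library. A correction for transcript length, a ribosomal RNA covariate (the log2 normalized count of Rn45s) and DESeq2 with a prior on fold changes were chosen after seeing the data. The replicate numbers were checked for pairing through the correlation of same-numbered deviations from each group's mean, which was −0.11, −0.02 and −0.09, so the numbers were not used as pairs. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

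The fit was tested on simulated data for 14287 genes with 3 libraries per group. At a 2-fold change limma recovered 9.90% of 101 genes, edgeR 10.9% and DESeq2 28.7%. At a 4-fold change they recovered 71.7%, 75.8% and 89.9% of 99 genes. Unchanged genes called were 6, 7 and 24. A list changed by 1.5-fold was the 1 list called of 35. Each simulated gene was drawn independently, so this cannot show how camera behaves where genes vary together. In the real data the estimated correlation was 0.50 for the sarcomere list and 0.45 for the immune list.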

Results

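The 3 control libraries held 12080965, 10580961 and 11952605 reads for replicates 1, 2 and 3, and the 3 Prrx1(R1A)-/- libraries 11878824, 11963532 and 14658584. R1A is the allele name in the labels, and the series title concerns a noncoding region that regulates Prrx1, so the comparison asks how atrial cardiomyocyte nuclei differ in animals with this allele on both chromosomes. Ribosomal RNA took 46.5%, 12.0% and 17.9% of reads in the controls and 26.7%, 28.9% and 39.8% in the Prrx1(R1A)-/- libraries (exact permutation p = 0.6). Control replicate 1 stood apart: across genes its correlation with the other 5 libraries was 0.890 to 0.908, against 0.958 between control replicates 2 and 3 and 0.930 to 0.938 among the Prrx1(R1A)-/- libraries. Xist, the RNA that silences one X chromosome in females, had 40451 to 58593 normalized counts in every library, and genes of the Y chromosome had at most 2 reads.

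Prrx1, a homeobox transcription factor of mesenchymal cells, averaged 192.7 ± 9.07 normalized read counts (SD, n = 3) in Prrx1(R1A)-/- nuclei against 344.0 ± 67.0 in controls, which is 44.0% lower. Each of the 3 Prrx1(R1A)-/- libraries (200.8, 194.4 and 182.9) lay below each of the 3 controls (415.2, 334.8 and 282.1). The gene (identifier 18933) lies on the minus strand of chromosome 1 at 163245119 to 163313710 in GRCm38. Its log2 fold change was −0.82 ± 0.25 (SE), with an unadjusted p of 0.0076 by limma for this gene named in advance. Over all genes the adjusted p was 0.270 by limma, so the difference did not pass the test. The exact permutation p was 0.1, the smallest that 3 against 3 libraries can give.

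The value of Prrx1 in control replicate 3, 282.1 normalized counts or 380.427 reads, was the 1 value in the table that was not a whole number of reads. In the authors' table Prrx1 had a log2 fold change of −1.17 with an adjusted p of 0.0034. It was the 1 gene there whose mean count (286.333) differed from the mean of its 6 deposited counts (268.4). It was also the 1 gene whose fold change over its standard error (4.33 in size) differed from its Wald statistic (2.43), and whose adjusted p lay below its p (0.0152). The 10 genes nearest to it in p had adjusted p from 0.236 to 0.238 in the authors' table. How the entry came to differ cannot be told from the values.

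**Figure D1:**
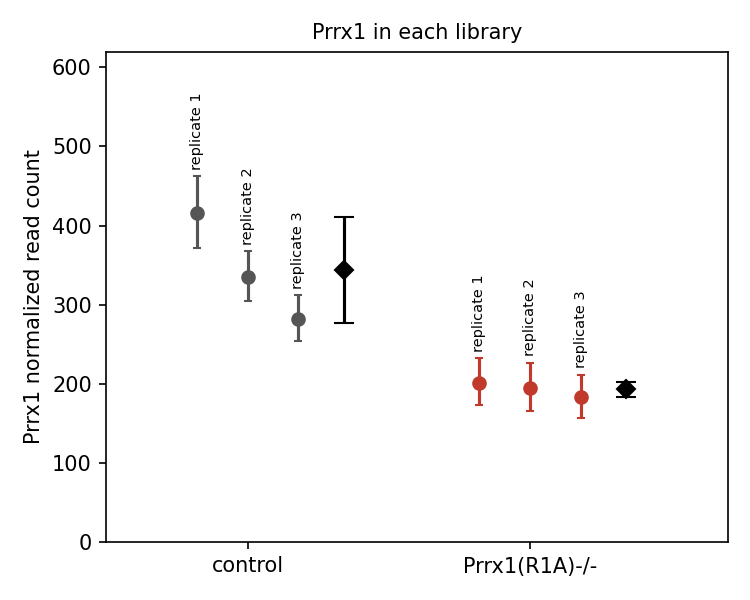
Prrx1 normalized read count (vertical axis) in each control and Prrx1(R1A)-/- library; circles are libraries with 95% Poisson intervals for counting error, and diamonds are group means ± SD (n = 3). The Prrx1(R1A)-/- libraries lie between 182.9 and 200.8, below the controls at 282.1 to 415.2.

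Counts assigned to the heart RNA Mhrt and the receptor gene Gpr17 were higher in Prrx1(R1A)-/- nuclei. Mhrt (identifier 791403; chromosome 14, 54968678 to 54974349, plus strand), a long noncoding RNA of the cardiac myosin heavy chain locus, had 3920 ± 1170 normalized counts (SD, n = 3) against 884.2 ± 188 in controls, a log2 fold change of 2.12 ± 0.26 (adjusted p = 0.039). Its exons overlap those of Myh7 on the other strand, so its reads could not be separated from Myh7 reads. Gpr17 (identifier 574402, chromosome 18, 31942997 to 31949636, minus strand), an orphan G protein-coupled receptor, had 2254 ± 251 against 750.9 ± 65.6 counts. Its log2 fold change was 1.58 ± 0.20 (adjusted p = 0.039 by limma). Its exons overlap those of Lims2 on the other strand, so its reads could not be separated from Lims2 reads.

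The other 8 named higher genes did not pass (adjusted p 0.088 to 0.094). Rbm20, which controls titin splicing, had a log2 fold change of 1.74 ± 0.25, Myo18b, a sarcomeric myosin that shares bases with an opposite-strand gene, 2.28 ± 0.35, and Alpk3, a cardiomyopathy kinase gene, 1.75 ± 0.28. Igsf9b (1.89), Rnf207 (1.74, overlapping Icmt), Dusp27 (1.79), Wnk2 (1.41) and Clip1 (1.26) were the others. Among lower genes, none passed either, with adjusted p 0.094 to 0.098. They included the small leucine-rich matrix proteoglycan Dcn (−1.22 ± 0.24; 3296 ± 636 against 7717 ± 1685 counts), the B cell chemokine Cxcl13 (−2.31 ± 0.42), the xenobiotic-metabolizing enzyme Cyp1b1 (−1.39 ± 0.24) and the macrophage receptor Vsig4 (−1.35 ± 0.26). Enpp2 (−1.31, overlapping Gm26684), Ctsc (−1.68), Hs2st1 (−1.52), Cd207 (−1.55), S100a6 (−1.16) and Aoc3 (−1.44) completed the 10.

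In all, limma called 2 genes higher and 0 lower of 14584; 973 were higher and 766 lower at an unadjusted p under 0.05, where chance gives 729.2 in both directions together. edgeR called 0 genes (1753 with an unadjusted p under 0.05), and DESeq2 called 244, 159 higher and 85 lower. The groups did not overlap for 2515 genes (17.2%, against 10% by chance). Without control replicate 1, limma called 1312 genes, 874 higher and 438 lower, and without any 1 of the other 5 libraries it called 0 (1022 to 1386 with an unadjusted p under 0.05). Both Mhrt and Gpr17 passed without control replicate 1 and with DESeq2, but not with edgeR (adjusted p = 0.056) or quantile scaling (0.055 and 0.062).

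Genes of the sarcomere and Z-disc, the contractile unit of muscle, were higher as a group: 33 of 34 measured members lay above 0, with a median log2 fold change of 1.12. Cardiac troponin T (Tnnt2) had 38206 ± 4960 against 13979 ± 3897 normalized counts (SD, n = 3; log2 fold change 1.48 ± 0.27), and Filip1 had 4544 ± 1186 against 1874 ± 182 (1.24 ± 0.24). No member passed over all genes (0 by limma, 24 with an unadjusted p under 0.05), and 23 passed when adjusted over the list alone. The list rose by camera with the preset correlation (adjusted p = 1.42e-21), but adjusted p = 0.40 with an estimated correlation. Control replicate 1 had the lowest level of these genes; without it the median was 0.89 and camera's adjusted p was 1.85e-11.

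Related cardiomyocyte lists pointed the same way, each called by camera at the preset correlation and none with an estimated one. Genes near atrial fibrillation risk loci had a median of 0.50 with 38 of 47 above 0 and 15 passing when adjusted over the list alone, 13 higher and 2 lower (adjusted p = 2.98e-07; adjusted p = 0.40 with an estimated correlation). Of these 47, 24 stood on another list too, and the other 23 had a median of 0.38. The atrial myosin heavy chain gene Myh6, a member, had 162697 ± 26707 against 53900 ± 6014 counts (1.59 ± 0.31), and Myo18b was the other member with the smallest p. Over the 20 alternatives the Myh6 log2 fold change ranged from 0.43 to 1.71. Leaving out 1 library gave 1.47 to 1.71, so the low end came from the processing. Myh6 and Myh7 (1.38 ± 0.27) are close paralogs, and each shares exonic bases with an opposite-strand gene. Genes of calcium handling had a median of 0.34, with 26 of 36 above 0 and 6 passing when adjusted over the list alone (adjusted p = 0.0013; adjusted p = 0.40 with an estimated correlation). Among them, the junctional protein Jph2 had 1.33 ± 0.24 and the calcium release channel Ryr2 had 1.34 ± 0.34. Potassium channel genes had a median of 0.39, with 18 of 27 above 0 and 5 passing when adjusted over the list alone, 4 higher and 1 lower (adjusted p = 0.0050; adjusted p = 0.40 with an estimated correlation); Kcnh2, which carries the rapid delayed rectifier current, had 1.42 ± 0.28 and the KATP channel subunit Abcc8 1.13 ± 0.21. Genes of cardiomyocyte stress and hypertrophy had a median of 0.32, with 22 of 28 above 0 and 4 passing when adjusted over the list alone (adjusted p = 0.0020; adjusted p = 0.40 with an estimated correlation), among them the smooth and cardiac muscle coactivator Myocd (1.41 ± 0.27) and the small heat shock protein gene Hspb7 (1.17 ± 0.23). Members on no other list had medians of 0.30 (32 calcium handling genes), 0.27 (17 potassium channel genes) and 0.17 (19 stress genes).

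Genes of the intercalated disc, which joins cardiomyocytes, had a median of 0.38 with 18 of 24 above 0 and 4 passing when adjusted over the list alone (adjusted p = 0.00078; adjusted p = 0.48 with an estimated correlation). Xirp1 had 1.47 ± 0.29 and the desmosome gene Dsp 1.14 ± 0.23, and the 17 members on no other list had a median of 0.28. Fatty acid oxidation genes had a median of 0.47 with 30 of 39 above 0 and 1 passing when adjusted over the list alone (adjusted p = 0.0012; adjusted p = 0.48 with an estimated correlation), with the coactivator Ppargc1b at 1.23 ± 0.26 and the nuclear receptor Esrrg at 1.31 ± 0.43 (0.81 without control replicate 1). Glycolysis genes had a median of 0.26 with 24 of 32 above 0 (adjusted p = 0.017; adjusted p = 0.48 with an estimated correlation); phosphofructokinase Pfkm, which overlaps Senp1, had 0.82 ± 0.29 and Pfkfb1, which overlaps Apex2, 1.89 ± 0.69. The circadian clock list had a median of 0.29 with 13 of 20 above 0 (adjusted p = 0.032; adjusted p = 0.48 with an estimated correlation), with Npas2 at 1.52 ± 0.53 and Usp2 at 0.72 ± 0.23. Atrial identity genes had a median of 0.39 with 16 of 25 above 0 (adjusted p = 0.035; adjusted p = 0.48 with an estimated correlation), but the 9 members on no other list had a median of −0.10. The atrial transcription factor Tbx5 had 0.86 ± 0.25 and Tbx20 −0.77 ± 0.23. The last 3 of these lists had 0 members passing when adjusted over the list alone by limma, with 5 glycolysis genes and 4 clock genes higher and, for atrial identity, 6 higher and 2 lower at an unadjusted p under 0.05. The calls for the intercalated disc (median 0.22, adjusted p = 0.052), fatty acid oxidation (0.09), glycolysis (0.22) and atrial identity (0.12) ended without control replicate 1, and those for glycolysis and atrial identity also without Prrx1(R1A)-/- replicate 1 (medians 0.25 and 0.35). The clock call ended without any 1 of control replicates 2 and 3 and Prrx1(R1A)-/- replicates 1 and 2 (medians 0.20 to 0.30).

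Among markers of other heart cells, which a sort for cardiomyocyte nuclei should remove, those of fibroblasts and immune cells were lower as groups, and those of endothelium did not pass the test. Fibroblast markers had a median of −0.61 with 18 of 20 below 0 and 8 passing when adjusted over the list alone (adjusted p = 1.04e-08; adjusted p = 0.40 with an estimated correlation). The matrix proteoglycans Dcn and Lum (−1.32 ± 0.28; 363.9 ± 92.3 against 921.6 ± 293 counts) had the smallest p. Immune cell markers had a median of −0.64 with 18 of 18 below 0 and 0 passing when adjusted over the list alone by limma, 9 of them at an unadjusted p under 0.05 (adjusted p = 7.29e-08; adjusted p = 0.44 with an estimated correlation). The lysosomal protease Ctss had −2.06 ± 0.55 and the Fc receptor Fcgr3 −1.10 ± 0.33. Endothelial and endocardial markers had a median of −0.01 with 8 of 19 above 0 (adjusted p = 0.493), but passed downward with quantile scaling (median −0.23, adjusted p = 0.021, against −0.90 for fibroblast markers); the junction protein Esam had −0.54 ± 0.22 and the receptor Tie1 0.48 ± 0.21. Without control replicate 1, which had the highest level of both, the fibroblast median was −0.38 (adjusted p = 0.00027) and the immune median −0.41 (adjusted p = 0.0055).

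Of the other cell type lists, none passed camera with all libraries. Epicardial markers had a median of −0.17 (adjusted p = 0.171; Aldh1a2, the retinoic acid synthesis enzyme, −0.69 ± 0.22, and Gpm6a −0.59 ± 0.23); they passed without control replicate 2 (median −0.25) or Prrx1(R1A)-/- replicate 3 (−0.35), with quantile scaling (−0.24) and with the ribosomal RNA covariate (−0.35, adjusted p = 0.00069), but had a median of 0.06 without Prrx1(R1A)-/- replicate 2. Adipocyte markers had a median of −0.31 (adjusted p = 0.371; Fabp4 −0.93 ± 0.43, Plin1 −1.73 ± 1.16); they passed with DESeq2 and a fold change prior (−0.33, adjusted p = 0.024), and had a median of 0.52 without control replicate 2. Schwann cell and neuron markers had a median of 0.22 (adjusted p = 0.493; Cdh19 −1.14 ± 0.43, and Cryab, which overlaps Hspb2, 0.52 ± 0.29). Smooth muscle and pericyte markers had a median of −0.05 but a mean of 0.08 and an upward test (adjusted p = 0.837; Cspg4 1.13 ± 0.30, Abcc9 −0.75 ± 0.22), and 2 passed when adjusted over the list alone, 1 in each direction. The blood list had 4 measured members, too few to test. Of the 7 lists tested, 2 were called; with quantile scaling 4 were, and with the ribosomal RNA covariate or the DESeq2 prior 3.

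**Figure D2:**
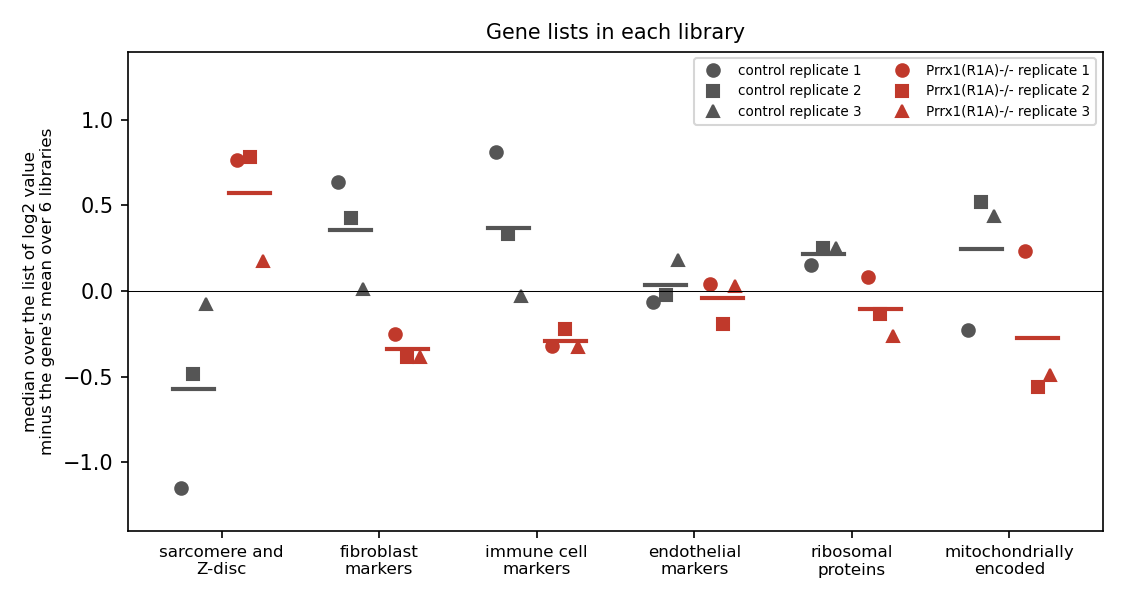
Level of 6 gene lists in each library: the vertical axis is the median over the list of each gene's log2 normalized count minus its mean over the 6 libraries, points are libraries (shape gives the replicate, grey control, red Prrx1(R1A)-/-) and bars are group means. Sarcomere levels lie from −1.15 to −0.08 in controls and 0.18 to 0.78 in Prrx1(R1A)-/- libraries, and control replicate 1 is the lowest there and the highest for fibroblast and immune cell markers.

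Matrix and mesenchymal genes were lower as well. Fibrillar matrix genes had a median of −0.32 with 30 of 37 below 0 (adjusted p = 0.00026; adjusted p = 0.48 with an estimated correlation). The collagen gene Col1a2 had 1717 ± 70.4 against 2927 ± 174 counts (−0.77 ± 0.19), and the gelatinase Mmp2 had −0.73 ± 0.21. Mesenchymal transcription factors, which include Prrx1, had a median of −0.28 with 13 of 15 below 0 (adjusted p = 0.036; adjusted p = 0.48 with an estimated correlation); Snai2 had −0.81 ± 0.40. Both lists had 0 members passing when adjusted over the list alone by limma, with 7 and 1 at an unadjusted p under 0.05. The 1 mesenchymal gene was Prrx1 itself, and the list was not tested without it. Members on no other list had medians of −0.29 (32 matrix genes) and −0.17 (12 mesenchymal factors). The mesenchymal call ended without control replicate 1 (median −0.05) and without any 1 Prrx1(R1A)-/- library (−0.37 to −0.20). Without control replicate 1 the matrix median was −0.14 (adjusted p = 0.046 by camera).

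The measured chromosomal neighbours of Prrx1 did not pass the test. The list had 16 measured genes, Prrx1 itself and 15 neighbours within 2 Mb, and 0 of the 16 passed when adjusted over the list alone by limma (lowest adjusted p = 0.061 over the list, for Prrx1 and Nme7). Of the 15 neighbours, 10 lay below 0 and 4 had an unadjusted p under 0.05. Nme7, which overlaps Atp1b1 and Blzf1, had 35.9 ± 9.66 against 98.0 ± 34.3 counts (−1.39 ± 0.43), and the flavin monooxygenase Fmo1 had 450.4 ± 74.7 against 742.3 ± 163.7 (−0.71 ± 0.25). Myoc (−0.99 ± 0.45), Suco (−0.55 ± 0.25), Kifap3 (−0.79 ± 0.39) and Vamp4 (−0.60 ± 0.31) were below 0 too, as were Fmo2 (−0.25), Dnm3 (−0.25), Selp (−0.26) and F5 (−0.32). Gorab, the nearest measured gene, had 0.29 ± 0.40, and Scyl3 (0.43), Prrc2c (0.23), Sele (0.12) and Pigc (0.06) were above 0. Of these, Myoc, Dnm3, Selp, F5 and Scyl3 share exonic bases with an opposite-strand gene. With quantile scaling Prrc2c was at −0.17. With edgeR and with DESeq2, Nme7 and Prrx1 passed when adjusted over the list alone, and without control replicate 1 Prrx1 and 7 neighbours did. Of those 7, Prrc2c was higher (0.42) and the others were lower. In that setting 3704 of all 14329 genes tested had an unadjusted p under 0.05 by limma. Some measured genes within 2 Mb were not on the list. Of these, Dpt (−1.11 ± 0.28) had the smallest p of the window (adjusted p = 0.197 over all genes by limma). Dnm3os (−0.88 ± 0.40) was below 0 too, while Slc19a2 (1.51 ± 0.77) and Gpr161 (0.86 ± 0.51) were above 0.

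**Figure D3:**
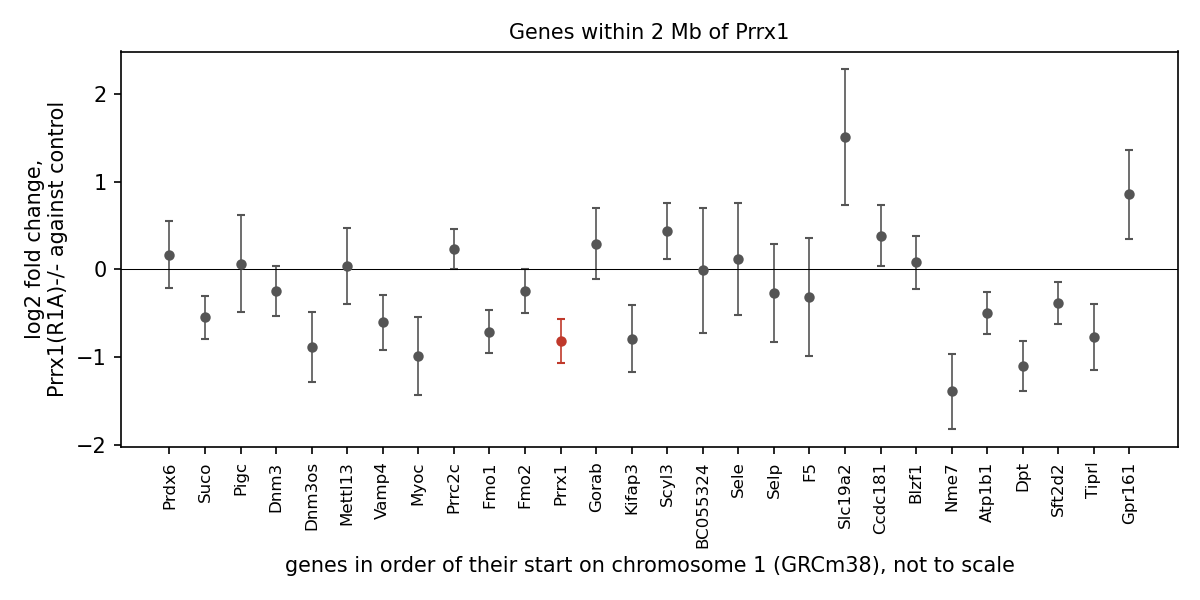
Log2 fold change (vertical axis, bars are SE, n = 3 per group) of the 28 measured genes within 2 Mb of Prrx1, in order of start on chromosome 1. Of the 27 genes other than Prrx1 (red, −0.82), 16 lie below 0, with a median of −0.25.

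The authors' deposited comparison table had 227 genes with an adjusted p under 0.05, 152 higher and 75 lower, Prrx1 among the latter. Of its 1900 genes, 1793 were tested here, and all 1793 had the same direction in the limma fit (Pearson r = 0.974 across genes, which are not independent replicates). Both rest on the same 6 libraries, and the table keeps only genes with a p under 0.05. The shared direction is therefore no independent support. The table gave Mhrt a log2 fold change of 1.89 and Gpr17 1.46. For genes other than Prrx1, DESeq2 with a prior on fold changes came within 0.0207 of the table's log2 fold changes. The limma values were fitted without such a prior, so the sizes are not directly comparable. Of the 227 genes, limma called 2 with all libraries (227 with an unadjusted p under 0.05), 205 without control replicate 1, and 0 without any 1 of the other 5 libraries (222 to 225 with an unadjusted p under 0.05). With all libraries edgeR called 0 of them (227 with an unadjusted p under 0.05) and DESeq2 213.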

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

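The length correction, the ribosomal RNA covariate and DESeq2 with a fold change prior were chosen after seeing the data; the other alternatives were fixed earlier. Prrx1 stayed below 0 without passing in all 20 alternatives (log2 fold change −0.95 to −0.65, adjusted p 0.060 to 0.681), and the sarcomere (median 0.75 to 1.46), fibroblast (−0.90 to −0.38) and immune (−0.96 to −0.40) lists kept direction and camera call in 20. The 2 called genes became 0 with quantile scaling (1680 with an unadjusted p under 0.05), edgeR (1753), the replicate number as a block (1361), an adjusted p under 0.01, and removal of mitochondrial, ribosomal protein and haemoglobin genes with quantile scaling (1678 with an unadjusted p under 0.05); 244 with DESeq2, 217 with DESeq2 and a prior, 1521 with library weights (control replicate 1 weighed 0.246) and 436 with the ribosomal RNA covariate. Leaving out 1 library gave 0 to 1312, the highest without control replicate 1; 1146 of these were among the 1521. Camera's 18 lists became 0 with an estimated correlation (2 with an unadjusted p under 0.05) and 0 by fry (lowest adjusted p = 0.207), though fry's test in either direction called 12; the other settings gave 12 to 24. Of the called lists, those that lost camera's call in some of the 20 settings were circadian clock and mesenchymal transcription factors (7 each), atrial identity (6), cell cycle, glycolysis and mitochondrially encoded genes (4 each), immediate early genes (3, of which 2 reversed), fatty acid oxidation (2), and fibrillar matrix and intercalated disc (1 each). Lists of other cell types went from 2 to 4 called with quantile scaling and 3 with the ribosomal RNA covariate or DESeq2 and a prior. Genes of the neighbour list, which includes Prrx1, that passed over the list alone went from 0 to 2 with edgeR, 2 with DESeq2 (Prrx1 and Nme7 in both), 1 with DESeq2 and a prior (Nme7), 7 with library weights (6 besides Prrx1) and 1 with the ribosomal RNA covariate (Prrx1), and ranged over 0 to 8 when leaving out 1 library (7 besides Prrx1 without control replicate 1). Of those last 7, Prrc2c was higher (0.42). Directions that reversed belonged to results that had not passed, except immediate early genes. With no filter these were ventricular genes (−0.37) and Notch (−0.011); with a filter at 50, smooth muscle (−0.047); with quantile scaling, Prrc2c (−0.17), heat shock (−0.039) and Notch (−0.035). With edgeR they were F5 (0.020), Pigc (−0.13) and Notch (0.051), with DESeq2 F5 (0.024), Pigc (−0.12) and Notch (0.053), and with DESeq2 and a prior F5 (0.014), Pigc (−0.084) and Notch (0.0013). Library weights reversed Pigc (−0.59), Schwann cell (−0.17), immediate early (0.22), heat shock (−0.030) and Wnt (0.033) results, the block reversed Notch (0.058), and the length correction Notch (0.014). The ribosomal RNA covariate reversed results for Sele (−0.24), Fmo2 (0.026), adipocyte (0.088), oxidative phosphorylation (0.045), heat shock (−0.016) and Notch (−0.072). For lists the direction is camera's, which can differ in sign from the median. Leaving out 1 library gave these ranges: Pigc −0.57 to 0.46, Sele −0.43 to 0.66, Selp −0.59 to 0.10, F5 −1.08 to 0.11, epicardial −0.35 to 0.063, endothelial −0.071 to 0.064, smooth muscle −0.14 to 0.18, Schwann cell −0.32 to 0.61, adipocyte −0.60 to 0.52, immediate early −0.64 to 0.29, oxidative phosphorylation −0.41 to 0.090, heat shock −0.10 to 0.28, Wnt −0.12 to 0.12, ventricular −0.55 to 0.28 and pacemaker −0.066 to 0.11 (in both camera's direction held), and Notch −0.028 to 0.17. List medians that moved without a change of sign were fibroblast −0.80 to −0.38, immune −0.96 to −0.41, mesenchymal −0.47 to −0.048, fibrillar matrix −0.35 to −0.14, atrial identity 0.12 to 0.74, fatty acid oxidation 0.088 to 0.55 and intercalated disc 0.22 to 0.52. Others were mitochondrially encoded −0.74 to −0.27, ribosomal protein −0.43 to −0.19, cell cycle −0.39 to −0.16, interferon −0.50 to −0.018, TGF-beta −0.24 to −0.051, cation channel 0.087 to 0.25, sodium channel 0.028 to 0.21, adrenergic 0.15 to 0.32, basement membrane 0.055 to 0.18 and clock 0.20 to 0.44. Among genes, Top2a ranged from −2.05 to −0.84, Plin1 −2.577 to −1.005, Fabp4 −1.55 to −0.58, Snai2 −1.06 to −0.52, Esrrg 0.81 to 1.61, Lrrc10 0.74 to 1.49, Pfkm 0.54 to 1.06 and Cryab 0.29 to 0.76. Of the neighbours, Fmo2 ranged from −0.52 to −0.093, Dnm3 −0.37 to −0.11, Gorab 0.093 to 0.63, Scyl3 0.10 to 0.61 and Prrc2c 0.098 to 0.42. The cause was not tested for any of these changes. In the simulated data limma found 9.90% of 2-fold changes. There 200 genes and 1 list were changed among 14287 genes, each drawn independently. The share found depends on that setting and was not measured for the real data.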

Other observations

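The comparison of endothelial with fibroblast markers, the tests of control replicate 1 as the cause, the refit of the Prrx1 entry and both tests of why Prrx1 was lower were chosen only after the results were seen, and the length correction and ribosomal RNA covariate after the data were seen. Cytoplasmic ribosomal protein genes and mitochondrially encoded genes were lower as groups in Prrx1(R1A)-/- nuclei. The ribosomal list had a median log2 fold change of −0.28 with 50 of 68 below 0 (adjusted p = 0.0020; adjusted p = 0.48 with an estimated correlation); it was −0.43 without Prrx1(R1A)-/- replicate 1 and −0.19 without Prrx1(R1A)-/- replicate 2. Rplp0, of the ribosomal stalk, had 133.8 ± 16.1 against 233.9 ± 34.6 normalized counts (SD, n = 3; −0.80 ± 0.27), and Rpl18, which overlaps Sphk2, −1.07 ± 0.34. All 7 measured mitochondrially encoded genes lay below 0 with a median of −0.52 (adjusted p = 0.011; adjusted p = 0.49 with an estimated correlation), among them the complex I genes ND5 (−0.60 ± 0.25) and ND6 (−0.63 ± 0.28), which overlap each other. Nuclear-encoded oxidative phosphorylation genes had a median of −0.19 and did not pass (adjusted p = 0.156), with the muscle isoform Cox6a2, which overlaps Itgad, at 1.19 ± 0.31 and Cox7a2l at −1.38 ± 0.38; without control replicate 1 their median was −0.41 and the list passed. Cell cycle genes had a median of −0.30 with 29 of 36 below 0 (adjusted p = 0.014; adjusted p = 0.48 with an estimated correlation), with the mitotic kinesin Kif11 at −1.31 ± 0.54 and Top2a at −1.37 ± 0.55 (−0.84 without Prrx1(R1A)-/- replicate 1 and −2.05 without Prrx1(R1A)-/- replicate 2). Immediate early genes, which respond within minutes to handling, had a median of −0.46 with 22 of 29 below 0 (adjusted p = 0.022; adjusted p = 0.73 with an estimated correlation). Klf6 had −0.72 ± 0.20 and Gadd45b −1.28 ± 0.42, but without control replicate 1 the list's median was 0.29. The mitochondrially encoded call ended without control replicate 2 or Prrx1(R1A)-/- replicate 2 or 3 (medians −0.46 to −0.36), and with the ribosomal RNA covariate, where the median was −0.11 (adjusted p = 0.303). That median was weakest without control replicate 3 (−0.27, adjusted p = 0.049) and strongest without Prrx1(R1A)-/- replicate 1 (−0.74). The cell cycle call ended without control replicate 1 (−0.34) or Prrx1(R1A)-/- replicate 1 (−0.16), and the immediate early call also ended without Prrx1(R1A)-/- replicate 1 (−0.26). In these 5 lists 0 members passed when adjusted over the list alone by limma; at an unadjusted p under 0.05, 5 ribosomal, 2 mitochondrially encoded, 3 cell cycle and 3 immediate early genes were lower, and 5 oxidative phosphorylation genes in each direction.

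The following signalling and channel lists did not pass camera with all libraries. Sodium channel genes had a median of 0.15 (adjusted p = 0.272). Calcium, HCN and other cation channels had a median of 0.16 (adjusted p = 0.060), with 1 passing when adjusted over the list alone; the L-type calcium channel Cacna1c had 1.48 ± 0.28. Adrenergic, muscarinic and cAMP genes had a median of 0.23 (adjusted p = 0.163; 0.15 without control replicate 3), with 3 passing when adjusted over the list alone, led by adenylyl cyclase Adcy5 (1.28 ± 0.24) and the anchoring protein Akap6 (1.46 ± 0.31). Pacemaker genes had a median of 0.04 (adjusted p = 0.651; the 5 on no other list −0.32; Cacna2d2 0.70 ± 0.22, Id2 −0.73 ± 0.29). The 5 measured ventricular genes had a median of −0.14, a mean of 0.21 and an upward test (adjusted p = 0.364), with 2 passing when adjusted over the list alone; the median was −0.55 without control replicate 1 and 0.28 without control replicate 3, and Myh7 had 1.38 ± 0.27 and Lrrc10 1.14 ± 0.40. Basement membrane genes had a median of 0.06 (adjusted p = 0.0505; Itga5 0.81 ± 0.22, Lama5 0.79 ± 0.23) and interferon response genes −0.33 (adjusted p = 0.065; Ddx58 −0.64 ± 0.23, Rsad2 −1.10 ± 0.53). TGF-beta and BMP genes had a median of −0.16 (adjusted p = 0.065); the BMP target Id1 had −0.98 ± 0.25, and Gdf6 had 13.8, 11.2 and 20.8 counts in controls and 1.09, 0 and 0 in Prrx1(R1A)-/- libraries. Wnt genes had a median of −0.03 (adjusted p = 0.731; Lgr6 1.97 ± 0.54, Sfrp1 −0.67 ± 0.22) and heat shock genes 0.07 (adjusted p = 0.769; Hspa5 −1.06 ± 0.28, Bag3 0.62 ± 0.21). Notch genes had a median of 0.06, a mean of −0.05 and an upward test (adjusted p = 0.994; Notch4 0.71 ± 0.21, Rbpj −0.78 ± 0.30). Without control replicate 3 the basement membrane (0.11), cation channel (0.21), interferon (−0.50) and TGF-beta (−0.24) lists passed, and without Prrx1(R1A)-/- replicate 3 the first 3 of these did (0.18, 0.21 and −0.50). Over all leave-outs of 1 library their medians ranged from 0.05 to 0.18, 0.09 to 0.25, −0.50 to −0.02 (interferon, weakest without Prrx1(R1A)-/- replicate 1) and −0.24 to −0.05 (TGF-beta, weakest without control replicate 1), and the cation channel median was lowest without control replicate 2. Of the sex chromosome list 2 genes were measured, both above 0.

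Sarcomere genes were higher and fibroblast markers lower together, which a lower share of all non-cardiomyocyte nuclei may explain only if the markers of each other cell type fall alike. The endothelial median lay 0.60 above the fibroblast median (permutation p = 0.0004 over genes, which are not independent). Between groups the gene-centred endothelial level went from 0.03 ± 0.13 to −0.04 ± 0.13 and the fibroblast level from 0.36 ± 0.32 to −0.34 ± 0.08 (SD, n = 3). With quantile scaling the endothelial median was −0.23 and the fibroblast median −0.90. The 2 lists thus did not fall alike in these libraries. The gene-centred measure was adopted after 2 others had been seen. These were the difference of list medians (exact p = 0.7) and of mean log2 values (−0.08 ± 0.33 against 0.49 ± 0.13, exact p = 0.1, the smallest possible). The explanation therefore stays undecided. Transcript length and the level of Rn45s are not the whole cause, since 95.4% of the sarcomere median was kept after length correction and 130.8% with the ribosomal RNA covariate. This covariate was Rn45s alone, so other carried-over RNA was not tested. Without control replicate 1, 79.3% of the sarcomere median and 62.2% of the fibroblast median were kept. Control replicates 2 and 3 still lay below the Prrx1(R1A)-/- libraries in sarcomere level (−0.49 and −0.08 against 0.18 to 0.78). They lay above them in gene-centred fibroblast level (0.43 and 0.01 against −0.39 to −0.25). By the list's median log2 value without centring, control replicate 3 (10.07) lay below the Prrx1(R1A)-/- libraries (10.25 to 10.34). A difference thus remained in the gene-centred levels. With 2 controls left, the role of control replicate 1 cannot be told apart from genotype for either part. A change in the nuclei that pass the PCM1 gate, of all other cell types or of fibroblasts and immune cells in particular, stays open. So does a change within cardiomyocytes.

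A candidate explanation for lower Prrx1 is less fibroblast RNA in the Prrx1(R1A)-/- libraries, given that Prrx1 is a mesenchymal gene. Prrx1 (−0.82) lay inside the range of the 20 fibroblast markers (5th to 95th percentile −1.35 to 0.20), and 25% of them were at or below it, but this range holds 0 and so would hold an unchanged Prrx1 too, which leaves the explanation undecided (the requirement that 0 lie outside was added after the value was seen). Another is loss of a region that acts on neighbouring genes too: the median of the 27 neighbours (−0.25) fell at percentile 2.36 of 10000 random sets of genes of like expression, whose 5th percentile was −0.21. The exact p over libraries was 0.3, and the requirement that the libraries separate was added after that value was seen. The random sets were matched on expression alone, so they cannot separate an effect on the region from the fall of fibroblast markers. This and the 3 libraries per group leave the explanation undecided. An effect of the allele on Prrx1 within cardiomyocytes stays open.

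The Prrx1 entry of the authors' table may not have been computed from the deposited counts in the way the others were. The refit was DESeq2 with a prior on fold changes and the deposited library factors. It came within 0.0264 of the Wald statistic for each of the other 1899 genes (median miss 0.0042). For Prrx1 it missed by 0.420. That fit gave Prrx1 a log2 fold change of −0.73 ± 0.26 and an adjusted p of 0.13. A count of about 312.6 reads in control replicate 3 would give the deposited Wald statistic. At 310 reads the log2 fold change was −0.65, against −1.17 in the table. Over the counts tried, 250 to 450 reads, the lowest log2 fold change was −0.80. It was reached at 450 reads, the highest count tried, and higher counts were not tested. The deposited mean count (286.333, against 268.4 from the deposited counts) would need more than 380.427 reads in control replicate 3, other counts unchanged. Within the counts tried, the deposited Wald statistic needed fewer. What led to the difference stays open.

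The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes called, 1 split of 10 gave as many as the real 2, namely the real split, and the highest of the others was 0. For lists called, 3 splits gave at least the real 18, and the highest of the others was 23. For lists of other cell types, 5 gave at least the real 2, and the highest of the others was 4. The split that set control replicate 1 with Prrx1(R1A)-/- replicates 2 and 3 had 1963 genes at an unadjusted p under 0.05, against 1739 for the real one, which points to a structure of the libraries beyond genotype. That split also parts the 3 libraries with the highest ribosomal RNA share (46.5%, 28.9% and 39.8%) from the others (12.0%, 17.9% and 26.7%), and those with the lowest level of mitochondrially encoded genes (−0.23, −0.56 and −0.49) from the others (0.52, 0.44 and 0.23). With the ribosomal RNA covariate, limma called 436 genes between genotypes.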
